A study of Oryza sativa with 12 samples.

How the data were processed

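Small RNA from rice (subspecies Indica, cultivar Pusa Basmati 1) was sequenced from roots and from seedlings at 14 days, per the labels, at 0 mM nitrogen (low N stress), 10 mM (control) and 100 mM (high N stress). The sample titles name the material only as root or seedling. Whether the seedling samples also held roots was not checked, so the tissue contrasts may set a part against a whole. Each of the 6 groups held 2 libraries, 12 in all, with replicates numbered 1 and 2. The labels do not say whether a replicate was a separate culture or a second library of the same RNA, so the p-values measure the spread between these libraries, part of which may be technical only. Total RNA was extracted with Trizol and made into libraries by Illumina's standard protocol, per the labels.

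The deposited tables list each distinct read sequence with its abundance and its length, and the abundances are raw counts per the file headers. The values were whole numbers from 1 up, each sequence stood once per table, and lengths ran from 18 to 25 nt. The authors' adapter trimming, quality filter and aligner are not given in the sources used here. Total reads per library ran from 5665807 (low N roots, replicate 1) to 8514343 (control roots, replicate 2), and reads of 20 to 24 nt from 3797924 to 6088280. Sequences read once made up 83.1% to 85.1% of the distinct sequences and 16.1% to 22.2% of the reads. A sequence absent from a library was limited to 3 counts of its reads. Reads carry no molecular identifiers, so intervals and limits cover counting error only.

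MicroRNA families were counted by exact identity to 108 mature sequences of 44 families, and 12 passenger-strand sequences were counted apart from them. The 2 listed forms of miR3979, and those of miR529, are unlike in sequence and were summed as mature. Whether they come from opposite strands was not checked. These sequences were written from general knowledge before the data were examined, not taken from a database, so a family read low or absent may be one whose listed form is wrong or minor. Families were grouped beforehand into 10 lists, namely development and transcription factors, auxin and root signalling, nitrogen response in the literature, phosphate starvation, sulfate starvation, copper with laccase and oxidase targets, small RNA machinery, triggers of reproductive phased small RNAs, 24-nt rice miRNAs, and families of the grass or rice lineage. Pieces of 5 tRNA and rRNA sequences served as a partial measure of RNA breakdown, since pieces outside the listed sequences were not counted.

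Counts were analysed with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). Library size was the number of reads of 20 to 24 nt times the TMM factor computed on the table of all distinct sequences. Low counts were removed with filterByExpr (minimum count 10, minimum total 15), which kept 35 of 44 families and 42222 sequences. Robust quasi-likelihood fits used all 12 libraries and 6 group means, which leaves 6 residual degrees of freedom. For the families the spread was pooled fully across families. Contrasts set low N and high N against the control within each tissue, the 3 root groups against the 3 seedling groups, and the nitrogen effects of the tissues against each other. Low N and high N were also set against each other within each tissue for the copper list. P-values were adjusted by the Benjamini-Hochberg method over all features tested, with a threshold of 0.05. Levels are reads scaled to library size (CPM), fold changes are on the log2 scale with their standard error (SE), and groups are given as mean ± standard deviation (SD). Shares of 21-nt and 24-nt reads were compared by a two-sided exact permutation test, with labels permuted within each nitrogen level or each tissue. The nitrogen tests have 36 arrangements and cannot give a p below 0.0556. The shares and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

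Families could be named when they passed the threshold and lay on the same side in all pairs of libraries across the groups. With more than 24 such families, the 12 largest rises and the 12 largest falls with at least 10 CPM in a group were to be named. The families of the nitrogen, phosphate, sulfate and copper lists were named in the nitrogen comparisons whatever their p. For single sequences, the 3 largest rises and the 3 largest falls with at least 50 CPM in a group were chosen. Because no genome sequence was used, a read could not be assigned to rice. A single sequence is therefore printed only where it reached 10 CPM in each of the 12 libraries or matched a listed sequence over 16 bases or more, a rule chosen after the values were seen. Comparisons of 24-nt reads in genome windows and the share of plastid reads were planned and not run for the same reason.

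Alternatives fixed before the data were examined were library size without TMM, TMM over the families alone, DESeq2 1.42.0 with its own size factors, other count filters, counting of end variants, a replicate block, fits within a tissue, other denominators of the shares, and leaving out each library in turn. End variants were reads of 19 nt or more that share bases 3 to 18 of a mature sequence. A covariate for the share of 18 to 19 nt reads, and a fit without sequences nearly confined to the control libraries, were added after the data were seen. The procedure was tested on simulated data with changes put into 50 sequences or 5 families each way. It found 45 of 50 sequences raised 2-fold, 37 of 50 lowered 2-fold, and 5 of 5 families each way. In that run 9 unchanged sequences of 38307 and 1 unchanged family were called. The exact test of shares gave p under 0.05 in 7 of 200 simulated draws with no difference and in 200 of 200 with a difference of 10 percentage points.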

Results

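Small RNA reads of 18 to 25 nt were measured in roots and seedlings of 14-day-old rice grown with 0 mM (low N), 10 mM (control) or 100 mM nitrogen (high N). The series concerns regulatory modules that respond to nitrate, so the nitrogen comparisons ask which microRNA families differ from the control in each tissue. Each of the 6 groups had 2 libraries. In replicate order, the root libraries held 5665807 and 6303700 reads at low N, 7228971 and 8514343 in the control, and 7840594 and 7260475 at high N. The seedling libraries held 8464140 and 7943082 reads at low N, 8366689 and 7984053 in the control, and 7447393 and 7684252 at high N. Reads of 20 to 24 nt made up 67.0% to 74.7% of each library. The first principal component of the sequence table held 62.0% of the variance and separated roots from seedlings, and the second held 10.6%. The third held 8.5% and set the control libraries of both tissues (34.0 to 58.3) apart from all others (-40.3 to 10.2). It cannot tell control libraries that stand apart from changes shared by low N and high N. Replicates differed beyond sampling noise in every group, with a chi-square per sequence of 1.25 to 1.84 in 5 groups and 4.86 in high N seedlings. High N seedling replicate 2 also had 13.1% of its reads at 18 to 19 nt, against 21.4% in replicate 1 and 15.9% to 23.7% in the other libraries.

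Reads of 24 nt, the usual length of plant heterochromatic small interfering RNAs, were the most frequent length in both tissues. They made up 20.96% ± 1.87 of all reads in roots and 24.6% ± 2.27 in seedlings (SD, n = 6 each). Among reads of 20 to 24 nt, the 24-nt share was 30.2% ± 2.11 in roots and 34.1% ± 2.43 in seedlings (n = 6 each, exact stratified permutation p = 0.0278, adjusted over the 6 share tests p = 0.167). The difference of -3.89 percentage points thus did not pass after adjustment, and was -2.73 without high N seedling replicate 2. The 21-nt share, the usual length of miRNAs, was 18.8% ± 0.886 in roots and 17.9% ± 1.39 in seedlings (n = 6 each, exact permutation p = 0.167, adjusted p = 0.25). Its difference of 0.91 points ran from 0.32 to 1.5 when each library was left out in turn. Against the control, the 24-nt share differed by 0.82 percentage points at low N (exact permutation p = 0.333, adjusted p = 0.4) and by 2.63 at high N (exact permutation p = 0.167, adjusted p = 0.25), with n = 4 per level. The high N difference rested on the high N seedling libraries, at 4.37 without replicate 1 and 0.89 without replicate 2, and the low N one ran from 0.14 without low N root replicate 2 to 1.51 without low N root replicate 1. The 21-nt share differed by -0.25 points at low N (exact permutation p = 0.722) and by -1.33 at high N (exact permutation p = 0.167), and with 4 libraries per level no p below 0.0556 was possible. The latter was -2.21 without high N seedling replicate 1 and -0.44 without replicate 2, and the former turned to 0.07 without low N root replicate 2. Adenine, the first base favoured by the 24-nt siRNA pathway, opened 43.3% ± 1.58 of 24-nt reads in roots and 44.1% ± 1.56 in seedlings. Uridine, favoured by miRNAs, opened 35.997% ± 1.77 of 21-nt reads in roots and 43.3% ± 1.64 in seedlings (n = 6 each, not tested).

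**Figure D1:**
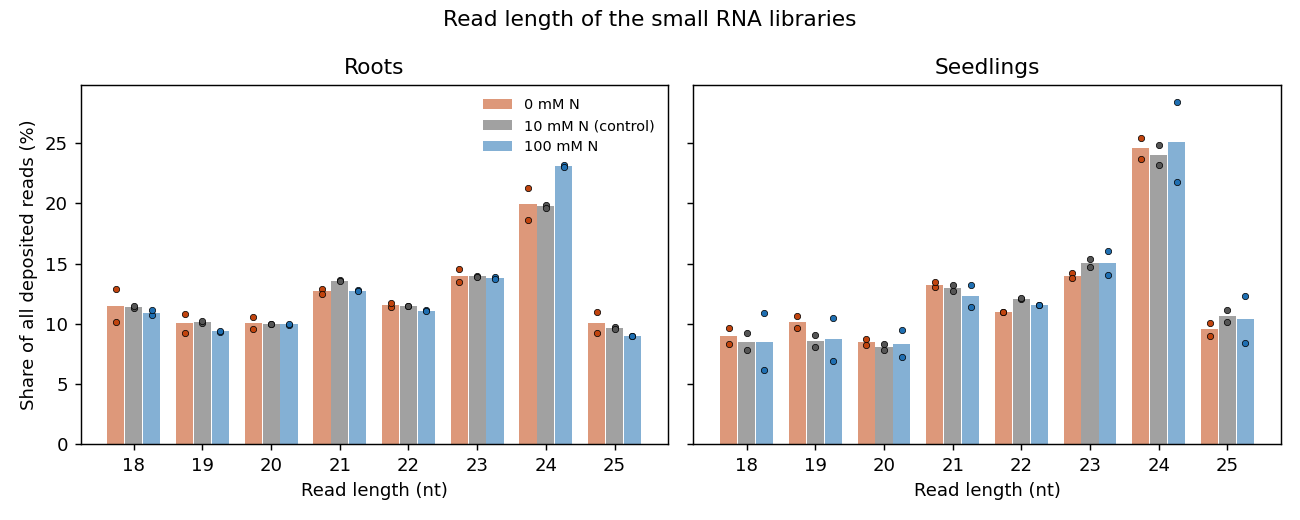
Share of all deposited reads (%, vertical axis) at each read length in nt (horizontal axis) for roots and seedlings at 0, 10 and 100 mM nitrogen, with bars for the mean of 2 libraries and a point for each library. Reads of 24 nt are the tallest class in each group, at 20.96% on average in roots and 24.6% in seedlings.

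In low N roots the families linked to phosphate starvation were lower and those linked to copper were higher than in control roots. miR827, which targets phosphate transporters of the SPX-MFS type in rice, fell 10.3-fold from 12.6 ± 0.795 to 1.19 ± 0.0316 CPM (SD, n = 2; log2 fold change -3.37 ± 0.47 SE, adjusted p = 1.55e-10). miR399, which targets the ubiquitin-conjugating enzyme PHO2, fell 7.52-fold from 5.09 ± 0.80 to 0.64 ± 0.242 CPM, the lower level resting on 2 and 4 reads (adjusted p = 3.23e-08). miR3979, a family described in rice, fell 10.1-fold from 55.2 ± 2.65 to 5.45 ± 0.25 CPM (adjusted p = 5.85e-24). miR408, which targets copper proteins of the plantacyanin type, rose 4.12-fold from 4.87 ± 0.176 to 20.2 ± 2.53 CPM (adjusted p = 1.8e-14).

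All 4 families of the copper list were called higher in low N roots. Beside miR408 these were miR528, a monocot family that targets ascorbate oxidase (2.30-fold, adjusted p = 0.0345), miR398, which targets copper/zinc superoxide dismutases (log2 fold change 1.00 ± 0.40), and miR397, which targets laccases (0.57 ± 0.21). Counting end variants ended the calls of miR398 (1.04 ± 0.44, adjusted p = 0.0662) and of miR393 below (0.28 ± 0.18, adjusted p = 0.203). Of the 8 families of the nitrogen list, miR393, which targets auxin receptors, rose (0.56 ± 0.23), miR827 and miR169, which targets NF-YA transcription factors, fell (-1.14 ± 0.32), and 5 did not pass. The values of those 5 were -0.74 for miR164, -0.16 for miR444, -0.14 for miR160, -0.02 for miR167 and 0.07 for miR171. With TMM over the families alone miR444, miR160 and miR167 turned and were called higher, at 0.40, 0.43 and 0.54 (edgeR adjusted p = 1.49e-05, 0.0274 and 0.000425). miR167 was called higher with DESeq2 too (0.38, adjusted p = 0.0488). miR395 of the sulfate list had no exact read in any library, which allows up to 0.0468 CPM over the 64167312 reads of 20 to 24 nt in all 12 libraries. That limit holds for the listed forms alone, since 154 reads were counted with end variants, and with these the family was higher in high N seedlings (2.05 ± 0.47, adjusted p = 0.00201) and did not pass in the other 3 nitrogen comparisons. The rise rested on 44 and 19 reads in high N seedlings against 5 and 10 in control seedlings. Elsewhere miR1432 rose (0.67 ± 0.16), and miR1425, which targets pentatricopeptide repeat proteins, fell (-0.74 ± 0.16). miR1850 also fell (-1.39 ± 0.26), a call that DESeq2 did not keep (adjusted p = 0.0525).

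By edgeR's quasi-likelihood test 16 of 35 families differed between low N and control roots, 6 up and 10 down, and the median log2 change of all families was -0.14. TMM over the families alone moved that median to 0.43 and DESeq2 to 0.26, and with these scalings 18 up and 5 down, and 10 up and 4 down, were called. The calls of miR399, miR827, miR1425, miR3979, miR408 and miR1432 held with all 4 scalings and without any 1 library. The rises of miR393, miR397, miR398 and miR528 held with all 4 scalings, yet were lost without 10, 5, 8 and 5 of the 12 libraries in turn, among them low N root replicate 2 and control seedling replicate 2 for each, with adjusted p up to 0.355, 0.521, 0.455 and 0.209. Without low N root replicate 2 the test called 8 families, and without high N seedling replicate 2 it called 21. miR169 lost its call with TMM over the families alone and with DESeq2 (adjusted p = 0.132) and without low N root replicate 2 (0.102). miR166, which targets HD-ZIP III transcription factors, and miR159, which targets GAMYB, were called lower (-0.50 ± 0.09 and -0.36 ± 0.15) but turned to 0.06 and 0.19 with TMM over the families alone, and counting end variants ended the call of miR159 (adjusted p = 0.196). The remaining calls, miR529 and miR1878, were lost with DESeq2 and without several libraries. miR529 rested on 3 reads against 15 (ratio 0.258, 95% exact interval 0.0480 to 0.914).

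In low N seedlings the same phosphate-linked families were lower and miR398 and miR408 were higher than in control seedlings. miR3979 fell 30.7-fold from 20.1 ± 2.67 to 0.624 ± 0.352 CPM (SD, n = 2; log2 fold change -4.94 ± 0.45 SE, adjusted p = 2.8e-21). The lower level rested on 5 and 2 reads, so the size of the fall is uncertain, at 51.2-fold without low N seedling replicate 1, 22.97-fold without replicate 2 and 10.8-fold with end variants counted. miR399 fell from 19.1 ± 2.22 to 3.15 ± 0.479 CPM (log2 fold change -2.59 ± 0.26, adjusted p = 1.65e-18), and miR827 fell 2.74-fold from 44.4 ± 3.61 to 16.2 ± 1.09 CPM (adjusted p = 5.87e-08). miR408 rose 3.37-fold from 33.0 ± 0.428 to 111.3 ± 4.52 CPM (adjusted p = 5.23e-21), and miR398 rose 3.22-fold from 49.9 ± 1.803 to 160.7 ± 11.8 CPM (adjusted p = 2.18e-22). miR160, which targets auxin response factors, rose 2.59-fold from 41.6 ± 2.87 to 107.8 ± 3.06 CPM (adjusted p = 6e-17).

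Of the copper list all 4 families were called higher in low N seedlings, but miR528 (0.66 ± 0.21) and miR397 (0.90 ± 0.28) lost their calls with TMM over the families alone and with DESeq2 (adjusted p = 0.714 and 0.522) and without control seedling replicate 2. Of the nitrogen list miR160, miR164, miR171, miR393 and miR444 rose and miR169 and miR827 fell. Among these rises only that of miR160 held with all 4 scalings, while miR164 (0.89 ± 0.23), miR171, which targets GRAS transcription factors (0.82 ± 0.19), miR393 (0.84 ± 0.18) and miR444, which targets MADS-box factors (0.58 ± 0.15), lost theirs with TMM over the families alone and with DESeq2. miR169 fell (-0.75 ± 0.27, adjusted p = 0.00976), a call lost without low N seedling replicate 2 or control seedling replicate 2 (adjusted p up to 0.101). miR167 did not pass (0.10), but was called lower at -0.38 with TMM over the families alone (edgeR adjusted p = 0.00719) and with DESeq2 (adjusted p = 0.0324). Of the development list miR159 rose 1.82-fold (0.86 ± 0.15), and of the 24-nt rice miRNAs miR1876 rose 2.05-fold (1.03 ± 0.14). miR1850 fell 2.83-fold (-1.50 ± 0.30).

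By the same test 26 of 35 families differed, 21 up and 5 down. The median log2 change of all families was 0.58, and moved to 0.04 with TMM over the families alone and 0.09 with DESeq2, so that 7 up and 10 down, and 5 up and 8 down, were called. The calls of miR399, miR827, miR1850, miR3979, miR159, miR160, miR398, miR408 and miR1876 held with all 4 scalings and without any 1 library. Without control seedling replicate 2 the number of calls was 15. miR396, miR1425 and miR1432 were called higher (0.46, 0.44 and 0.38) but turned to -0.02, -0.04 and -0.09 with TMM over the families alone. Of the other 7 called rises, miR394 and miR535 were lost with DESeq2, and miR168, which targets AGO1 (0.58 ± 0.15), miR172, miR529, miR820 and miR1884 were lost with TMM over the families alone as well. Counting end variants ended the calls of miR820 (0.26) and miR1432 (0.22), and the value of miR529 moved from 1.12 to 1.73 without control seedling replicate 1.

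**Figure D2:**
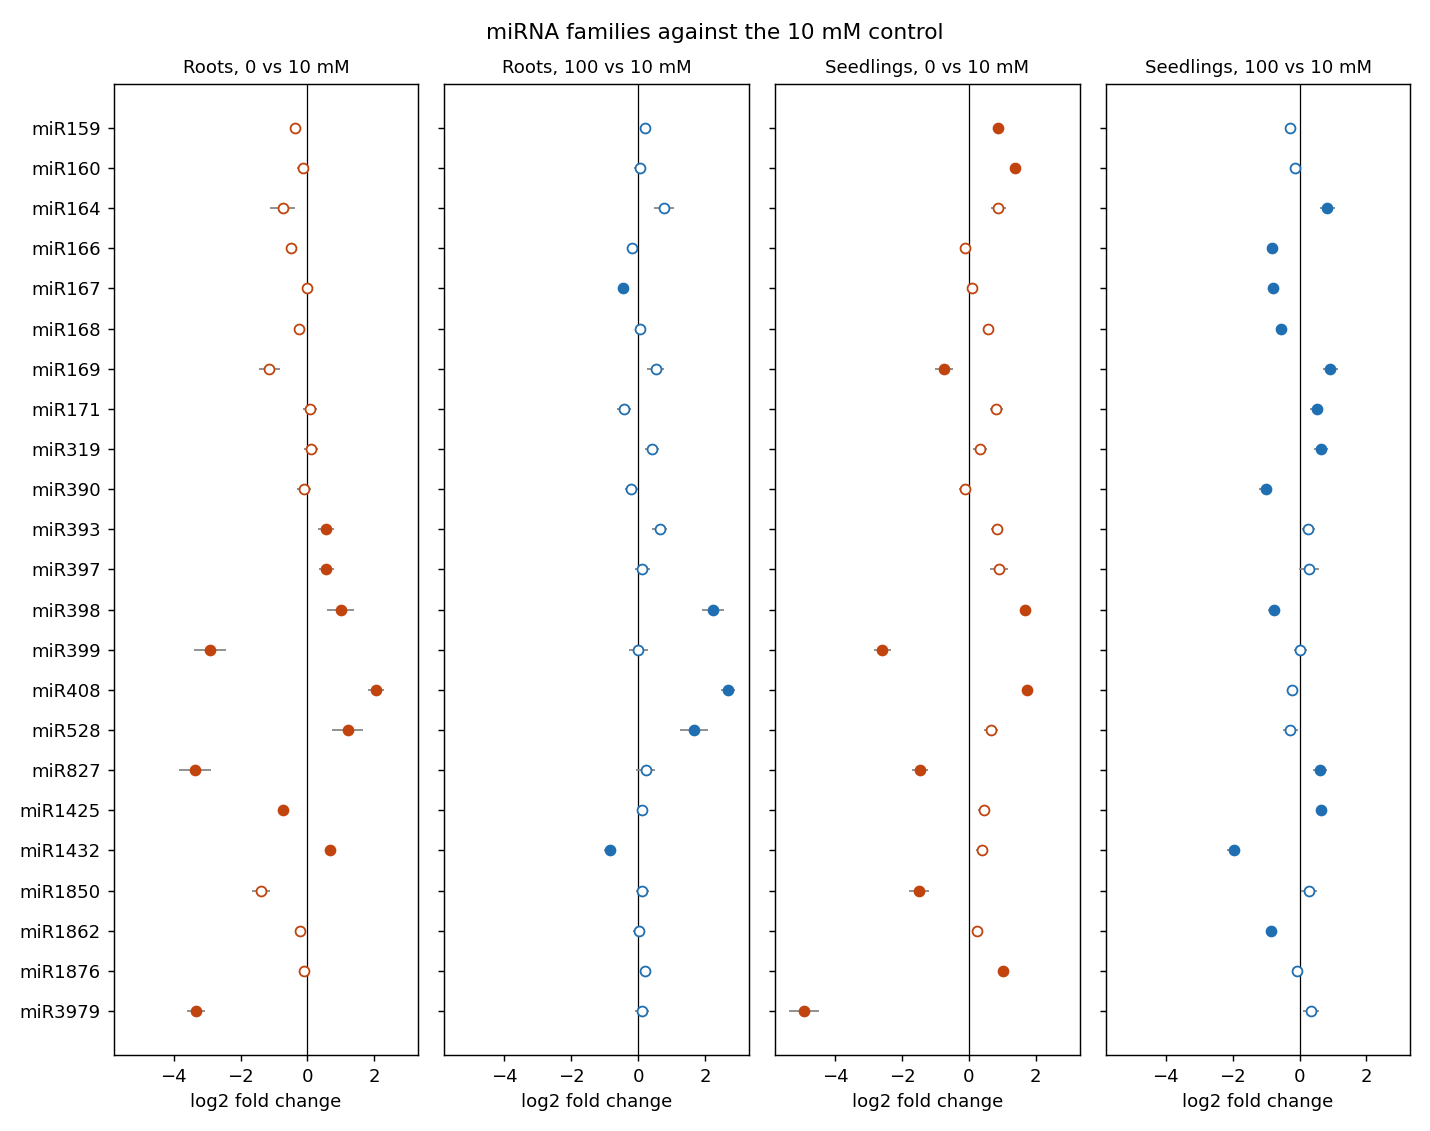
Log2 fold change against the 10 mM control (horizontal axis, with SE bars) of 23 miRNA families in roots and seedlings at 0 and 100 mM nitrogen. Filled points are calls that held with all 4 scalings, and open points were not called or were lost with another scaling, such as miR166 in low N roots, which turns from -0.50 to 0.06, and miR159, which turns from -0.36 to 0.19. The change farthest from 0 is that of miR3979 in low N seedlings, at -4.94, which rested on 5 and 2 reads and was -3.44 with end variants counted.

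In high N roots the copper-linked families were again higher than in control roots, while the phosphate-linked families were near the control. miR408 rose 6.43-fold from 4.87 ± 0.176 to 31.5 ± 1.04 CPM (SD, n = 2; log2 fold change 2.68 ± 0.22 SE, adjusted p = 1.1e-24). miR398 rose 4.71-fold from 1.48 ± 0.55 to 7.20 ± 0.63 CPM (adjusted p = 1.06e-09), and miR528 rose 3.19-fold from 1.28 ± 0.26 to 4.11 ± 1.28 CPM (adjusted p = 0.000855). The fourth copper family, miR397, did not pass (0.13 ± 0.21). Its value counts the listed form alone, at 8.47 ± 2.72 CPM in control roots, while the shifted 22-nt form TTGAGTGCAGCGTTGATGAACC, at 16.4 ± 1.57 CPM there, rose to 152.5 ± 9.61 CPM at high N (log2 fold change 3.22 ± 0.14, adjusted p over all sequences = 7.99e-27). miR1432 fell 1.79-fold from 41.3 ± 2.10 to 23.1 ± 0.68 CPM (adjusted p = 1.75e-05), and miR167, which targets auxin response factors, fell 1.38-fold (adjusted p = 0.0178). miR399, miR827 and miR3979 did not pass, with log2 values of 0.01, 0.22 and 0.11.

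Of the nitrogen list miR164, which targets NAC transcription factors, and miR393 rose in high N roots (0.78 ± 0.29 and 0.65 ± 0.23) and miR167 fell. The others did not pass, at 0.52 for miR169, 0.04 for miR160, -0.18 for miR444 and -0.42 for miR171, beside miR827 above. Of the development list miR396, which targets growth-regulating factors, rose (0.49 ± 0.15). By edgeR's test 8 of 35 families differed, 6 up and 2 down. The calls of miR408, miR398 and miR1432 held with all 4 scalings and without any 1 library. miR528 and miR167 held with all 4 scalings, and miR528 was lost without high N root replicate 2 or control root replicate 2 (adjusted p up to 0.0998), miR167 without high N root replicate 1 or control root replicate 2 (0.116). miR164, miR393 and miR396 lost their calls with at least 1 other scaling and without 8 to 10 of the 12 libraries, and miR167 and miR396 lost their calls when end variants were counted (-0.25 and 0.33). Fitted on root libraries alone, 13 families were called, and the count ran from 4 without control root replicate 2 to 15 without either high N seedling library.

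In high N seedlings miR1432 fell 3.93-fold from 42.6 ± 0.67 to 10.9 ± 3.23 CPM (SD, n = 2; log2 fold change -1.97 ± 0.19 SE, adjusted p = 3.55e-19). Counted with end variants its log2 value was -1.21. miR166, the most abundant family, fell 1.77-fold from 36318 ± 1639 to 20526 ± 2400 CPM (adjusted p = 1.67e-15). Also lower were miR390, which starts the trans-acting siRNAs that target auxin response factors (2.02-fold), miR167 (1.72-fold) and miR168 (1.46-fold). miR169 rose 1.89-fold from 10.3 to 19.6 ± 4.76 CPM (adjusted p = 0.000306) and miR164 rose 1.78-fold from 9.28 ± 0.37 to 16.6 ± 2.63 CPM (adjusted p = 0.00131). miR827 rose 1.52-fold to 67.6 ± 5.28 CPM, and miR398 fell 1.71-fold to 29.3 ± 7.41 CPM.

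Of the 8 families of the nitrogen list miR164, miR169, miR171 and miR827 rose, miR167 and miR444 fell, and miR160 (-0.14) and miR393 (0.26) did not pass. Of the phosphate list miR399 did not pass (0.02). Of the copper list only miR398 passed (-0.77 ± 0.16), with 0.28 for miR397, -0.21 for miR408 and -0.28 for miR528. Of the small RNA machinery list miR168 and miR162, which targets DCL1, fell (-0.55 and -0.51). Elsewhere miR1425 and miR319, which targets TCP factors, rose (0.63 and 0.65), and miR1862 fell (-0.86 ± 0.14). In all 17 of 35 families differed, 6 up and 11 down. The calls of miR164, miR169, miR166, miR167, miR168, miR390, miR398, miR1432 and miR1862 held with all 4 scalings and without any 1 library. Those of miR171, miR319, miR827 and miR1425 held with all 4 scalings but not without control seedling replicate 2, nor those of miR171, miR319 and miR827 without control seedling replicate 1. miR171 was lost without 10 of the 12 libraries, all but the 2 high N seedling libraries (adjusted p up to 0.247), and miR319 also without high N seedling replicate 1 (0.21, adjusted p = 0.299). Counting end variants ended the calls of miR168 (-0.10), miR171 (0.05) and miR319 (0.23). miR156, miR162, miR396 and miR444 lost their calls with TMM over the families alone, which moved the median of all families from -0.09 to 0.28 and called 15 up and 7 down. High N seedling replicate 2, which stood apart in read length, left all 17 calls in place when it was left out.

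**Figure D3:**
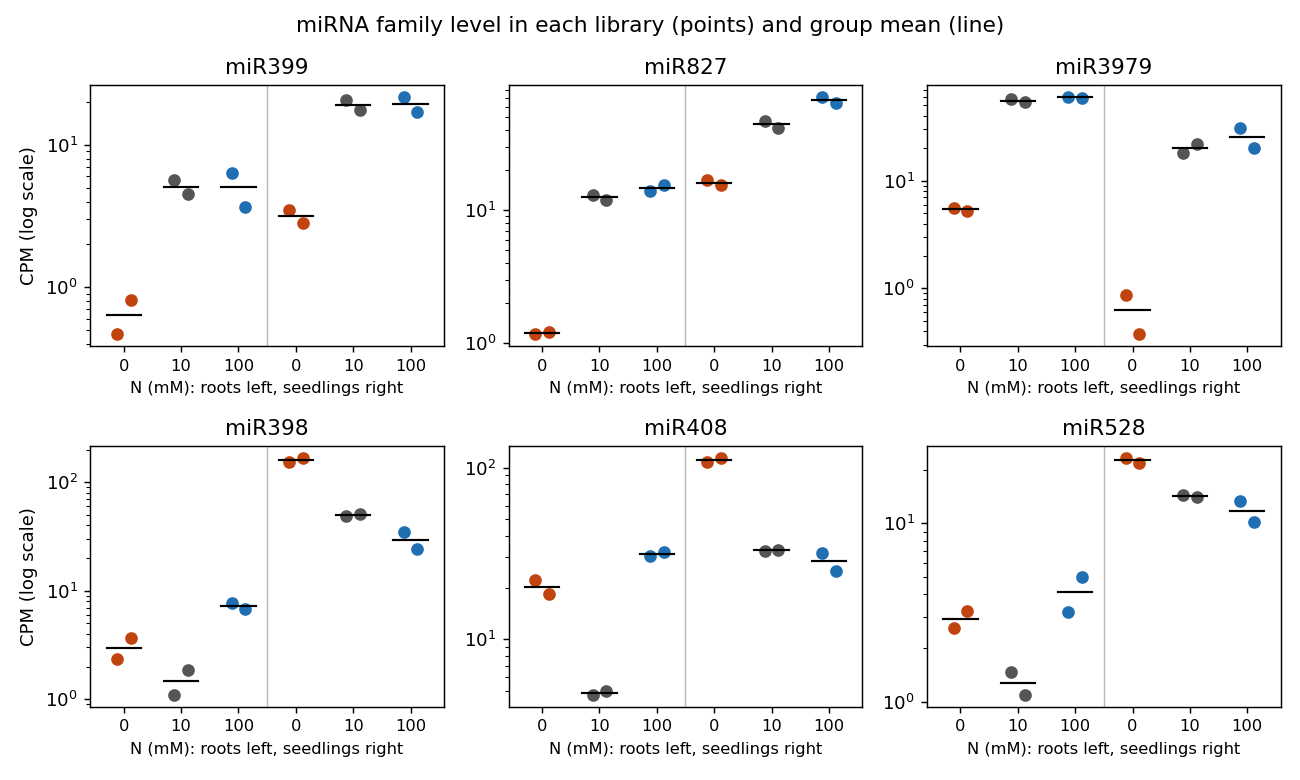
Level in CPM (vertical axis, log scale) of 6 miRNA families in each library (points) with the group mean (line), at 0, 10 and 100 mM nitrogen (horizontal axis), roots at the left and seedlings at the right of each panel. miR399, miR827 and miR3979 are lowest at 0 mM in both tissues, and miR408 is higher at 0 mM than at 10 mM in both, at 20.2 against 4.87 CPM in roots and 111.3 against 33.0 in seedlings. These directions did not turn under any of the 4 scalings.

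The effect of high N differed between roots and seedlings for 3 of the 4 copper-linked families. The log2 change in roots minus that in seedlings was 3.01 ± 0.36 for miR398 (SE, n = 2 per group, adjusted p = 1.57e-13), 2.90 ± 0.28 for miR408 (adjusted p = 1.42e-18) and 1.95 ± 0.48 for miR528 (adjusted p = 0.000366). For miR397 it did not pass (-0.15 ± 0.37, adjusted p = 0.784), although its shifted form did (3.68 ± 0.19, adjusted p over all sequences = 1.38e-22). In all 10 families differed by edgeR's interaction test, 9 higher and 1 lower in roots, while TMM over the families alone gave 7 higher and 8 lower. Beside these, miR1432, miR396 and miR166 (1.13, 0.89 and 0.63) and miR171 (-0.93) held with all 4 scalings and without any 1 library, although miR171 turned to 0.10 when end variants were counted. For low N 14 families differed between tissues, 1 higher and 13 lower in roots. Only miR3979 (1.60 ± 0.67, adjusted p = 0.0452) held with all 4 scalings, and it was lost without 8 of the 12 libraries (adjusted p up to 0.212), with end variants counted (0.17, adjusted p = 0.749) and with a replicate block (1.61, adjusted p = 0.057), and was 2.37 without low N seedling replicate 1. With TMM over the families alone, 16 families were called, all higher in roots, and the median difference moved from -0.47 to 0.61. No family of the copper list passed this test of the low N response, while the shifted form of miR397 did (1.11 ± 0.19).

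Between tissues, averaged over nitrogen levels, most families were called lower in roots, although with DESeq2 the median of all families was near level (-0.06 against -0.98). Pieces of 5 tRNA and rRNA sequences, a partial measure of RNA breakdown, also differed between the tissues without overlap, at 3.61% ± 0.253 of reads in roots and 2.85% ± 0.0974 in seedlings (SD, n = 6 each), and the contrast was not adjusted for them. Pieces outside the listed sequences were not counted, so whether breakdown as a whole differed between the tissues cannot be told. Nested sequences of 18, 19 and 25 nt, which open with the same bases and are not all in that count, were not higher in control roots. They stood at 5026, 9818 and 7737 CPM of all reads there, against 5936, 10008 and 9904 in control seedlings. At low N the 25-nt one was higher in roots (7349 against 6556). Whether they are rRNA pieces was not checked. miR398 was 19.05-fold lower, at 3.89 ± 2.71 CPM in roots and 80.0 ± 63.5 in seedlings (SD, n = 6 each; log2 fold change -4.25 ± 0.13 SE, adjusted p = 2.24e-83). miR394, which targets an F-box protein of leaf development, was 9.30-fold lower, at 5.08 ± 1.79 against 47.3 ± 17.5 CPM (adjusted p = 1.93e-45). miR528 was 6.25-fold lower. miR396, miR393, miR164, miR167 and miR1862 were 3.10-fold to 3.22-fold lower. miR390 and miR162 were 2.504-fold and 2.20-fold lower. All 4 tested families of the auxin list were called lower in roots, and none of these turned with another scaling. Also called lower were 8 of 8 families of the nitrogen list, of which miR169 and miR171 turned to 0.33 and 0.16 with DESeq2, and 3 of 3 of the small RNA machinery list, of which miR168 and miR820 turned to 0.64 and 0.01. Of the development list 8 of 10 were called lower, of which miR156, miR159, miR166 and miR171 turned with DESeq2 (0.23, 0.50, 0.59 and 0.16), and of the 24-nt rice miRNAs 5 of 5, of which miR1876 and miR1878 turned (0.66 and 0.19).

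By edgeR's test 33 of 35 families differed between tissues, 4 up and 29 down in roots, and in 13 of the falls no root library overlapped a seedling library. Of those 13, the 10 families from miR398 to miR162 above held with all 4 scalings and without any 1 library, while miR160, miR444 and miR1884 lost their calls with DESeq2. TMM over the families alone moved the median of all families to -0.21. With these scalings 10 of the 33 called families turned in at least 1, and 16 of 27 and 13 of 25 calls were lower in roots. The 4 families called higher in roots, miR3979, miR397, miR1850 and miR1432 (1.91, 1.04, 0.56 and 0.43), kept that direction in all 4 scalings but their libraries overlapped between tissues. The families miR2118 and miR2275, triggers of phased small RNAs in reproductive tissue, stayed near 0, at most 2.07 ± 0.534 CPM.

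Among single sequences, a 22-nt form shifted from the listed miR397, TTGAGTGCAGCGTTGATGAACC, rose in roots at both extremes of nitrogen. It was at 16.4 ± 1.57 CPM in control roots, 62.5 ± 3.90 at low N (log2 fold change 1.93 ± 0.15) and 152.5 ± 9.61 at high N (3.22 ± 0.14; SD, n = 2). In seedlings it rose at low N (0.82 ± 0.12) and fell at high N (-0.46 ± 0.12), from 127.7 ± 1.74 CPM in the control. In roots against seedlings, the largest rises were GCACGCCTGTCGGGACCCGA (3.20, 6912 ± 1980 against 788 ± 339 CPM, n = 6), its longer form GCACGCCTGTCGGGACCCGAAA (2.88), both matching none of the lists, and GGCCGAGGGCACGCCTGCCTGGGC, a piece of 5.8S rRNA (2.74). The lists hold only 5 tRNA and rRNA sequences, so whether the first 2 are pieces of another rRNA was not checked. The other chosen sequences matched none of the lists and were under 10 CPM in some library, too low to be assigned to rice here, so they are not printed. Of 15792 tested 24-nt sequences, 931 rose and 211 fell in high N roots, and of the 7960 that open with adenine, 515 rose and 46 fell. Of the 26430 sequences of 20 to 23 nt, 1154 rose and 1062 fell. The counts at 24 nt were 668 and 320 without TMM, 171 and 115 with DESeq2, 757 and 253 without 39 sequences nearly confined to the control libraries, and 387 and 419 of 80022 with a minimum count of 3, which turned the balance. In roots against seedlings, 2124 of the 24-nt sequences were higher and 5806 lower, and 3230 and 4468 without TMM.

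Of 42222 sequences tested, 869 rose and 821 fell in low N roots, 2085 and 1273 in high N roots, 2963 and 3150 in low N seedlings, 4148 and 3903 in high N seedlings, and 9300 and 12960 in roots against seedlings (edgeR, adjusted p under 0.05). Which side held more was not stable, and changed in 17 of 44 recounts with another setting and all libraries. In high N roots the counts were 1572 up and 1871 down without TMM, 614 and 649 with DESeq2, 998 and 2416 with a minimum count of 3, and 1759 and 1540 without the 39 control-confined sequences. In low N roots they were 533 and 997 with a minimum count of 3, in low N seedlings 3453 and 2293 without TMM, and in high N seedlings 2922 and 3738 with a minimum count of 3. In the tissue contrast they were 13512 and 10543 without TMM, which moved the median log2 change from -0.07 to 0.14, and 3902 and 3542 with a minimum count of 50. Among 54 tested mature sequences of the list fixed beforehand, 12 were called in low N roots over all sequences and 17 adjusted over the list alone. The corresponding counts were 11 and 13 in high N roots, 28 and 35 in low N seedlings, 22 and 26 in high N seedlings, and 46 and 48 between tissues. Low N and high N share a control, which by itself links their changes. Across sequences, which are not independent, the changes at low and high N correlated at r = 0.643 in roots and 0.427 in seedlings, against 0.461 and 0.51 in simulations with a shared control only, while the covariances were 0.888 and 0.474 against 0.228 and 0.0966. Across families r was 0.459 in roots and -0.144 in seedlings, against 0.444 and 0.461, and the covariances were 0.436 and -0.116 against 0.0551 and 0.0216. The covariance thus exceeded its simulated value in all of these but the seedling families. The simulations hold no change, so control libraries that stand apart would also raise the covariance above them. The excess therefore cannot show that low N and high N share changes.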

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

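The tests of scaling, of the control libraries and of the read length profile given here were chosen after the results were seen, and the scaling tests of the copper families, of the balance in high N seedlings and of the control-confined sequences and the tests of control roots and control seedlings were also rewritten after a first version had given its value. The test of another source of reads was written before its result.

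The copper-linked families miR397, miR398, miR408 and miR528 were higher than the control in low N roots and low N seedlings, and 3 of them in high N roots. The scaling of a library moves every family alike, so each called family was set against the median of the 31 tested families off the copper list. In low N roots 4 of 4 and in high N roots 3 of 3 called families lay above that median by more than 2 SE, from 0.78 ± 0.33 for miR397 to 2.26 ± 0.35 for miR408 and from 1.56 ± 0.44 for miR528 to 2.57 ± 0.25 for miR408 on the log2 scale, which argues against scaling as the whole cause there. The rises of miR397, miR398 and miR528 in low N roots were nevertheless lost without 5, 8 and 5 of the 12 libraries in turn, and that of miR528 in high N roots without 2. In low N seedlings miR398 and miR408 lay above it (1.25 ± 0.33 and 1.31 ± 0.33, 2 of 2), while 0 of 2 did so for miR397 and miR528 (0.46 ± 0.40 and 0.22 ± 0.36), so scaling may account for the calls of these. Low control seedlings as the whole cause are argued against for miR398 and miR408, since 2 of 2 were called higher in low N than in high N seedlings with all 4 scalings, a comparison without the control (log2 2.46 ± 0.15 and 1.97 ± 0.16, and 1.59 ± 0.16 and 1.09 ± 0.16 with TMM over the families alone). For miR397 and miR528 0 of 2 held, with -0.25 ± 0.29 and 0.07 ± 0.19 under that scaling, so for these family counts low control seedlings cannot be told apart from an effect of low N. Nor can control roots that stand apart, since 0 of 4 families were called between high N and low N roots with all 4 scalings. There miR398 went from 1.24 ± 0.30 to 0.61 ± 0.37, miR408 from 0.64 ± 0.18 to 0.02 ± 0.19, miR397 from -0.44 ± 0.21 to -1.07 ± 0.23 and miR528 from 0.47 ± 0.37 to -0.15 ± 0.37 with TMM over the families alone. The shifted form of miR397, which the family count leaves out, was higher in low N than in high N seedlings (1.28 ± 0.12, adjusted p = 5.66e-13), which goes against low control seedlings as the whole cause for that form. It was higher in high N than in low N roots (1.29 ± 0.13), against the direction of the listed form. Other scalings were not tried for it. A response of copper-linked families to nitrogen remains a hypothesis, and copper supply was not measured.

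In high N seedlings most called families were lower than in the control. Whether the scaling of the libraries set that balance cannot be told apart from an effect of high N, since most calls were lower in 2 of the 3 other scalings, at 41.2% rising calls without TMM and 35.3% with DESeq2, while TMM over the families alone, which centres the families and so sets their balance itself, gave 68.2%. In the test of the read length profile of high N seedling replicate 2, 17 of 17 calls held both with the share of 18 to 19 nt reads as a covariate and without that library. A lone library was assumed to vary like the other groups, whose replicates differed less, so keeping the calls decides little. Leaving out each library in turn moved miR156 between -1.02 and -0.42 and miR390 between -1.48 and -0.74, and no called fall turned. The profile is thus argued against as the cause of these directions, not of their sizes. The falls of miR166, miR167, miR168, miR390, miR398, miR1432 and miR1862 held with all 4 scalings, and an effect of high N on them stays open and untested otherwise.

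A set of 39 sequences was nearly confined to the control libraries, with at least 10 CPM in control roots and at most 5% of that level in the other root groups. They held 0.182% of control root reads and 0.0478% of control seedling reads, and 38 and 37 of the 39 fell in low N and high N seedlings too. Reads from another source, such as another organism or library, may be the cause, but the test left it open, since the SD of their log2 ratio between tissues was 0.835 of that of matched sequences and 89 of 1000 random sets were as low. Whether these sequences set the scaling of the root libraries also stayed open, since without them 9.82% of the other calls in high N roots were lost. No biological explanation was tested for them.

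The low N effect, in roots minus seedlings (log2), differed between tissues by the interaction test for 14 families. The values were -1.22 for miR159, -1.51 for miR160, -1.63 for miR164, -1.93 for miR394, -3.00 for miR529, -2.01 for miR820, -1.91 for miR827, -1.18 for miR1425, -1.13 for miR1876 and 1.60 for miR3979. With end variants counted, the values were 0.17 for miR3979 and -0.19 for miR171, no longer called, -0.71 for miR820 and -1.96 for miR529. Those of miR3979, miR820 and miR529 were 2.37, -2.69 and -3.58 without low N seedling replicate 1, low N root replicate 1 and control seedling replicate 1 respectively. The values of miR166 (-0.40), miR168 (-0.85), miR171 (-0.75) and miR444 (-0.73) turned with TMM over the families alone and with DESeq2. None of the 13 negative values was called lower with either of these scalings, under which 16 and 7 families were called, all higher in roots. Among these calls were miR166 with TMM over the families alone (0.64, edgeR adjusted p = 5.95e-22) and with DESeq2 (0.47, adjusted p = 0.00317). miR444 was also called higher with TMM over the families alone (0.31, adjusted p = 0.0301).

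The high N effect, in roots minus seedlings (log2), differed by the same test for 10 families. The values were 3.01 for miR398, 2.90 for miR408, 1.95 for miR528, 1.13 for miR1432, 0.89 for miR396, 0.88 for miR1862, 0.81 for miR390, 0.63 for miR166, 0.60 for miR168 and -0.93 for miR171. Counting end variants ended the calls of miR390 (0.74), miR168 (0.30) and miR171 (0.10). The calls of miR1862, miR390 and miR168 were lost with at least 1 other scaling (adjusted p up to 0.159, 0.223 and 0.255). Leaving out a library ended that of miR168 in 10 of 12 cases (adjusted p up to 0.206) and that of miR390 in 5 (0.303), among them control root replicates 1 and 2, control seedling replicate 2 and high N seedling replicate 2 for both.

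Signals above the control also stood in reads that the comparisons of 20 to 24 nt leave out. Of the 6 sequences tested, those of 18, 19 and 25 nt that open with the same bases are nested. Their tests are thus not independent, and whether they are rRNA pieces was not checked. The 19-nt sequence GGGCCTGTAGCTCAGAGGA was higher in low N seedlings (log2 4.90 ± 0.21, adjusted p = 2.05e-18), low N roots (1.65 ± 0.22) and high N roots (0.94 ± 0.22). The 18-nt sequence ACCGACCTGCTCGACCCT was higher in low N seedlings (0.90 ± 0.18). Against these 4 rises, 6 of the 24 tests of 6 such sequences were called lower than the control, from -0.54 to -0.99, among them CCAGCCCCGCGTCGCACGGATTCGT in high N seedlings (-0.99 ± 0.16, adjusted p = 4.46e-05) and CACACGACTCTCGGCAACGGATATC in low N seedlings (-0.65 ± 0.16, adjusted p = 0.00366).

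Passenger strands, counted apart from the mature families, were called above the control in 8 of 32 tests and below it in 1. The miR408 passenger was higher in low N roots (2.79), high N roots (4.71) and low N seedlings (1.63 ± 0.34). In roots it rested on 12 reads at low N against 2 in the control, a ratio of 7.75 (95% exact interval 1.73 to 71.3), and on 54 against 2 at high N, a ratio of 29.7 (7.83 to 252). Of the 12 reads, 2 were in low N root replicate 1 and 10 in replicate 2, so the low N rise rested mainly on 1 library. These intervals pool the libraries of a group and leave out the spread between them. The passengers of miR168 (1.00), miR390 (1.02) and miR166 (0.81) were higher in low N seedlings, and so was 1 of the 2 miR396 passengers, GTTCAATAAAGCTGTGGGAAA (1.13), read 6 to 20 times per seedling library, while the more abundant GGTCAAGAAAGCTGTGGGAAG did not pass (0.32, adjusted p = 0.275). The miR166 passenger was also higher in high N seedlings (0.92), where mature miR166 fell, and lower in low N roots (-0.98 ± 0.37, adjusted p = 0.0428).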

How the results depend on the processing

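The covariate for 18 to 19 nt reads and the fit without control-confined sequences were chosen after the data were seen. Of 115 counts and shares recomputed without leaving out a library, 80 counts stayed within 1.5 times and 17 shares kept their direction and side of the threshold. A count of similar size need not hold the same calls. In 18 of 80 such counts the larger side, up or down, changed. With TMM over the families alone the low N tissue difference went from 1 up and 13 down to 16 and 0, with 3 shared calls, low N roots from 6 and 10 to 18 and 5 (11 shared), and high N seedlings from 6 and 11 to 15 and 7 (13 shared). The cause of the changes below was not tested, except that fewer or more sequences were tested where the count filter changed.

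Numbers of called families moved to 17 (TMM over the families alone) and 13 (DESeq2) from 26 in low N seedlings, to 13 (root libraries alone) and 16 (covariate) from 8 in high N roots, and to 7 (DESeq2) from 14 and 17 (covariate) from 10 for the low N and high N tissue differences. Numbers of called sequences moved with DESeq2 to 643 in low N roots, 1263 in high N roots, 2748 in low N seedlings and 3462 in high N seedlings. With a minimum count of 50 they were 984, 2025, 3549, 4851 and, between tissues, 7444 of 11415 tested. With a minimum count of 3 the tissue contrast gave 38017 of 144470, and with the covariate low N roots gave 2906. The 24-nt share difference between tissues was -1.90 over distinct sequences (exact permutation p = 0.139).

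With TMM over the families alone, log2 values turned in low N roots for miR159 (0.19), miR160 (0.43), miR166 (0.058), miR167 (0.54) and miR444 (0.40), in low N seedlings for miR167 (-0.38), miR396 (-0.0163), miR1425 (-0.0378) and miR1432 (-0.0933), and in the low N tissue difference for miR166 (0.64), miR168 (0.19), miR171 (0.30) and miR444 (0.31). With DESeq2 they turned for miR159 (0.028) and miR167 (0.38), for miR167 (-0.38), miR396 (-0.0209), miR1425 (-0.043) and miR1432 (-0.0979), and for miR166 (0.47), miR168 (0.0271), miR171 (0.13) and miR444 (0.14). With end variants counted, miR171 turned in the high N tissue difference (0.10).

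Leaving out each library in turn, families called ranged from 8 to 21 in low N roots, 4 to 15 in high N roots, 15 to 30 in low N seedlings, 13 to 22 in high N seedlings, 32 to 35 between tissues, and 10 to 17 and 8 to 18 for the tissue differences at low and high N. Sequences called ranged from 870 to 2667, 1686 to 5294, 3870 to 7827, 4703 to 8219 and 23311 to 26127. The 24-nt share difference between tissues ranged from -5.05 to -2.73 (exact permutation p from 0.00926 to 0.0648) and the 21-nt one from 0.32 to 1.4998 (exact permutation p from 0.037 to 0.556). Against the control, the 24-nt share difference ranged from 0.14 to 1.51 at low N and 0.89 to 4.37 at high N, and the 21-nt one from -0.58 to 0.07 and -2.21 to -0.44. A lone library left in a group was assumed to vary like the other groups. With a replicate block, 14 families were called in low N roots, 9 in high N roots, 26 in low N seedlings, 18 in high N seedlings, and 13 and 10 for the tissue differences at low and high N, and the calls of miR393 and miR1878 in low N roots and of miR3979 in the low N tissue difference ended, although replicate numbers did not pair the libraries (r of -0.41 to 0.56 over 15 pairs of groups). Depth limits families under a few CPM, such as miR399 in low N roots, and genome windows of 24-nt reads and the plastid share were not run.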

Other observations

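The tests reported here of random splits of the libraries were written before their results, and the splits that keep replicates together and the values on RNA pieces, end variants and shared controls were chosen after the data were seen.

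Pieces of 5 tRNA and rRNA sequences made up 3.61% ± 0.253 of reads in roots and 2.85% ± 0.0974 in seedlings (SD, n = 6 each). Pieces of one arginine tRNA were 0.292% ± 0.0268 of reads in low N seedlings, against 0.0702% ± 0.00985 in control seedlings and 0.0471% ± 0.0175 in high N seedlings, and 0.116% to 0.1196% on average in the root groups (SD, n = 2 each). Pieces of the listed 5.8S rRNA sequence, the largest of the 5 sources, were lower in low N seedlings. They were 1.65% ± 0.0195 of reads in low N, 1.99% ± 0.0405 in control and 1.85% ± 0.107 in high N seedlings. In the root groups they were 2.33% ± 0.0247, 2.43% ± 0.0973 and 1.94% ± 0.00269 in that order. Nested sequences of 18, 19 and 25 nt, which open with the same bases, stood at 5936, 10008 and 9904 CPM of all reads in control seedlings. Together these exceed the 1.99% of the 5.8S count there, so it does not hold all of them. Whether they are 5.8S pieces was not checked. Pieces of 5S rRNA were 0.579% ± 0.00656 in low N and 0.583% ± 0.0413 in high N seedlings against 0.458% ± 0.00850 in the control. The sources thus did not move together with nitrogen, and the nitrogen comparisons were not adjusted for them. The 19-nt sequence GGGCCTGTAGCTCAGAGGA stood at 16498 ± 1611 CPM (of all reads of 18 to 25 nt, without TMM) in low N seedlings, against 531 ± 50.9 in control and 571 ± 218 in high N seedlings, and at 35.4 ± 5.62, 11.02 ± 1.63 and 19.2 ± 3.64 in low N, control and high N roots. It was not matched to a gene here.

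Some families were read mainly as end variants of the listed form. miR395, which targets genes of sulfate assimilation, had 154 end-variant reads and rose with them in high N seedlings (log2 fold change 2.05 ± 0.47 SE, edgeR adjusted p = 0.00201), with 1.26 ± 0.54 in high N roots (adjusted p = 0.085). The rise in seedlings rested on 44 and 19 reads at high N, which are unlike, against 5 and 10 in the control. The siRNAs of the tasiR-ARF family had 1275 end-variant reads against 1 exact read, and miR530 had 1 end-variant read and no exact read. Counted with end variants, miR529, which targets SPL transcription factors, rose in low N and high N seedlings (1.39 and 1.07) and fell in low N and high N roots (-0.57 and -0.58). miR319 counted so rose in low N roots, high N roots and low N seedlings (0.55, 0.59 and 0.60). For these counts no values with the other scalings are given. In low N seedlings the median change of all families, counted exactly, was 0.58, so the miR319 value there may reflect scaling.

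Low N and high N were each compared with the same control libraries, and controls of 2 libraries cannot be divided between them. A shared control by itself raises the agreement, so counts that assume independence are no reference for these numbers. In roots 4 families rose in both, none fell in both and 1 was called in opposite directions, with a correlation across families of 0.459 against 0.444 in simulations with a shared control alone, and a covariance of 0.436 against 0.0551. In seedlings 3 rose in both, none fell in both and 7 were called in opposite directions, with -0.144 against 0.461 and a covariance of -0.116 against 0.0216. Among all sequences 384 rose and 534 fell in both root comparisons and 77 went in opposite directions, with a correlation of 0.643 against 0.461 and a covariance of 0.888 against 0.228. In seedlings 868 rose and 1248 fell in both and 458 went in opposite directions, with a correlation of 0.427, below the simulated 0.51, and a covariance of 0.474, above the simulated 0.0966. The simulations, which hold no change, gave 0 calls shared by both comparisons in each case. Control libraries that stand apart would also exceed them, so they cannot show changes shared by low N and high N.

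For the contrast of roots with seedlings, random splits of the 12 libraries into groups of the same sizes were compared with the real one. The model held nitrogen level and the side of the split as additive terms, in place of the 6 group means. For families, 1 of 100 splits drawn from 462, the real one, gave as many calls, 27 against at most 19 in the others. For all sequences, 1 of 40 splits, the real one, gave as many, 19409 against 0. These splits would exclude chance only if the libraries were independent, which the labels do not say of replicates. Splits that keep the replicates of a group together number 10, too few for a share under 0.05. Among them 3 gave as many families, 27 against at most 27 in the others, and 1, the real one, as many sequences, 19409 against at most 239. The other 2 with 27 families part roots from seedlings at low N, and have roots and seedlings of each other level on one side. With nitrogen level in the model, both test only low N roots against low N seedlings and are the same test.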
